A study of Drosophila melanogaster with 2 samples.

How the data were processed

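Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole embryos of a transgenic *Drosophila melanogaster* line that carries Repo fused at its C-terminus to green fluorescent protein (GFP). Per the labels, embryos of both sexes of 0 to 24 hours were used, chromatin was sheared by sonication to 200 to 800 bp, and an antibody against GFP was used. The series holds 1 group of 2 biological replicates, numbered 1 and 3 in the labels. No second genotype, stage or treatment was analysed here, so the comparisons are between the replicates and between parts of the genome within the peak lists.

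Peak lists on the genome builds dm3 and dm6 were used. Per the labels and the text files deposited with them, each replicate has its own list of peaks and background made as input for an irreproducible discovery rate (IDR) analysis. A pooled list was made from both replicates together, and an optimal list of peaks was kept after IDR thresholding; the peak lists were derived from the alignments and from 1 further file that the text does not describe. The control-normalized and other signal tracks listed there were not used here. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each of the replicate and pooled lists holds 30000 peaks, and the optimal list on dm6 holds 2697.

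The values in the lists are the authors' own. The signal value of each peak comes from the authors' peak caller, and its scale is not stated. It was used to rank, filter or describe peaks within a list. Between lists it was compared only by rank correlation, in a plot of the replicates, and at equal rank between builds. The deposited lists also give the −log10 of a q-value per peak, which took its highest value in 2625 of the 2697 optimal peaks and was therefore not used for ranking. The deposited offset of each summit from the peak's start, in bp, gave the summit position. Peaks on dm6 were placed 1-based on the reference; no coordinates were converted between builds, and the dm3 lists were compared only by number, chromosome and signal value. The number of reads per library is unknown here. The lists hold no read counts, so no interval below covers sequencing depth; Wilson 95% intervals on shares of peaks cover counting error only.

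The reference was the dm6 genome sequence with the Ensembl BDGP6 annotation. Every dm6 peak lay on chromosome 2L, 2R, 3L, 3R, 4 or X and inside the length of its reference chromosome. The annotation holds 13945 protein-coding genes on these chromosomes. Of the genes in the fixed lists, 343 were matched by symbol or older symbol; 3 listed genes were not matched and were not used here.

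Agreement of the replicates was measured by counting summits that lay inside a peak of the other list. Chance overlap came from 1000 random circular shifts of the summits within each chromosome, with a one-sided permutation p. The N highest peaks of each replicate by signal value, with N equal to the 2697 optimal peaks, were compared because the full lists contain background. Spearman's rho of the signal values was computed across matched peaks with a bootstrap 95% interval and without a p, since peaks are not replicates.

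Each summit was assigned to the first class that applied: promoter (within 500 bp of a transcription start site, TSS, of a protein-coding gene), 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic. Shares were compared with the 27302 pooled-list peaks whose summit lies in no optimal peak, called weak peaks below, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over classes.

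A gene counted as bound when an optimal summit lay between 2000 bp upstream of its start and its end. Such a summit can lie in the promoter of another gene. For each of 15 gene lists, the number of bound genes was compared with 10000 random lists of the same size drawn from protein-coding genes of the same decile of interval length, with a one-sided permutation p for more bound genes and Benjamini-Hochberg adjustment over lists. A one-sided test for fewer bound genes, adjusted in the same way, was not in the design and was added after seeing the data. The 3 glial lists together were compared with the neuron list by Fisher's exact test, two-sided. The threshold was an adjusted p of 0.05.

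For 14 fixed motifs and for each of the 2080 six-base words (a word counted with its reverse complement), the share of windows of 100 bp either side of the summit that hold the sequence on either strand was compared with windows of the same size centred 1000 bp to either side. Fisher's exact test, two-sided, was used with Benjamini-Hochberg adjustment over motifs or over words. These windows differ in base composition: GC content was 39.4% at summits, 43.1% in the flanks and 48.0% at the summits of weak peaks.

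Genes named in the text were set by a rule before the data were examined, as were the gene lists, motifs and tests. The rule takes repo first, then up to 12 bound genes of the glial lists by highest signal value, 4 bound genes of any other list past its test and 2 of any other list, and the genes whose TSS is nearest to the 10 optimal peaks of highest signal. It also takes every fixed motif and the 5 words of smallest p. Neighbours of repo, other genes of a list and the gene families in the closing section were named after their values were seen. For the closing section, 22 gene families set by symbol were screened after the data were seen, and all 22 were kept in the table and in its Benjamini-Hochberg adjustment (permutation p, two-sided). A first table kept 12 of them, chosen with their values in view; the other 10 were put back before the text was finished, which moved the ratio of the constitutive families together from 1.83 to 1.78.

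Alternatives set in advance changed the threshold, the build, the matching rule, the promoter distance, the gene interval, the background of random lists, the window size and the background of motif tests, or used the N highest peaks of 1 replicate in place of the optimal list. The split of gene lists, motifs and words by distance to a TSS beyond the motif test planned for distal summits, and the alternatives for location classes and named genes, were added after seeing the data.

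The tests were checked on simulated data. With no effect planted, 4% of 200 random lists of 93 genes had a p of at most 0.05. With a rise of 4 times planted, 100% passed (median ratio 3.43), and of 200 lists of 18 genes with a planted rise of 2 times 56% passed before adjustment. The simulated lists were drawn at random from all protein-coding genes. Flank windows split at random gave 0 words of 2080 and 0 motifs of 14 past the threshold, and 5 of 5 words planted in a small part of the windows were recovered, with 11 further words past the threshold. The overlap test called 0% of 20 unrelated peak sets and 100% of 20 sets that shared 50.3% of their summits. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.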

Results

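Repo is a homeodomain transcription factor of glial cells, the support cells of the nervous system. The data list the places in the genome where GFP-tagged Repo was recovered from whole *Drosophila* embryos of 0 to 24 hours, in 2 biological replicates, 1 and 3. The embryos contain glia among many other cell types, and the design asks where the tagged protein was found and how far the replicates gave the same places. Positions are on dm6.

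The optimal list held 2697 peaks with a median width of 396 bp, covering 0.972 Mb. They were the 2697 pooled-list peaks of highest signal. Signal values, which are the authors' own, ran from 84.0 to 1703 with a median of 123. The 10 highest peaks lay closest to the transcription start sites (TSSs) of Ugalt, cbt, CG14100, px, CG11050, Lk6, PNPase, ph-p, Chro and mRpL41. These genes include a Golgi sugar transporter (Ugalt), a Polycomb group protein (ph-p), a chromosome-associated protein (Chro) and a mitochondrial ribosomal protein (mRpL41). The highest peak, with a signal of 1703, was at X 2703693 to 2704077, in the promoter 33 bp from the TSS of Ugalt. The next, at 2L 480892 to 481292 with a signal of 1698, lay in an intron of ush, which encodes a cofactor of GATA factors, 1398 bp from the TSS of cbt. The peaks of CG11050 and Lk6 also lay in introns, 1038 and 969 bp from the TSS, and the other 7 were promoter peaks. Each of the 10 peaks ranked among the first 10 in both replicates' own lists; Ugalt ranked 2 in replicate 1 and 1 in replicate 3.

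Both replicates gave largely the same strong peaks. Of the 2697 optimal peaks, 2692 (99.8%, Wilson 95% interval 99.6 to 99.9%) had their summit inside a peak of replicate 1's full list and 2686 (99.6%, 99.3 to 99.8%) inside one of replicate 3's. Within the 2697 highest peaks of each replicate these numbers were 2230 (82.7%) and 2302 (85.4%), against means of 20.4 and 19.7 under circular shifts. The replicates' own 2697 highest peaks shared 1881 (69.7%, 68.0 to 71.4%), against a shifted mean of 19.3. Each of these overlaps had a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. The optimal list was made from these replicates, so only the overlap of the replicates' own lists is independent of it.

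The shared fraction fell with rank. Of the 100 highest peaks of replicate 1, 85 were in the 100 highest of replicate 3; of the 1000 highest, 770 (77.0%) were shared, and of all 30000, 13846 (46.2%). Signal values had a Spearman's rho of 0.632 (bootstrap 95% interval 0.603 to 0.659) across the 2681 optimal peaks found in both replicates, and of 0.586 (0.573 to 0.599) across all 13846 matched peaks. Among the 10360 matched peaks outside both sets of 2697, rho was 0.269. These correlations are across peaks of 2 libraries, and peaks are not independent replicates.

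**Figure D1:**
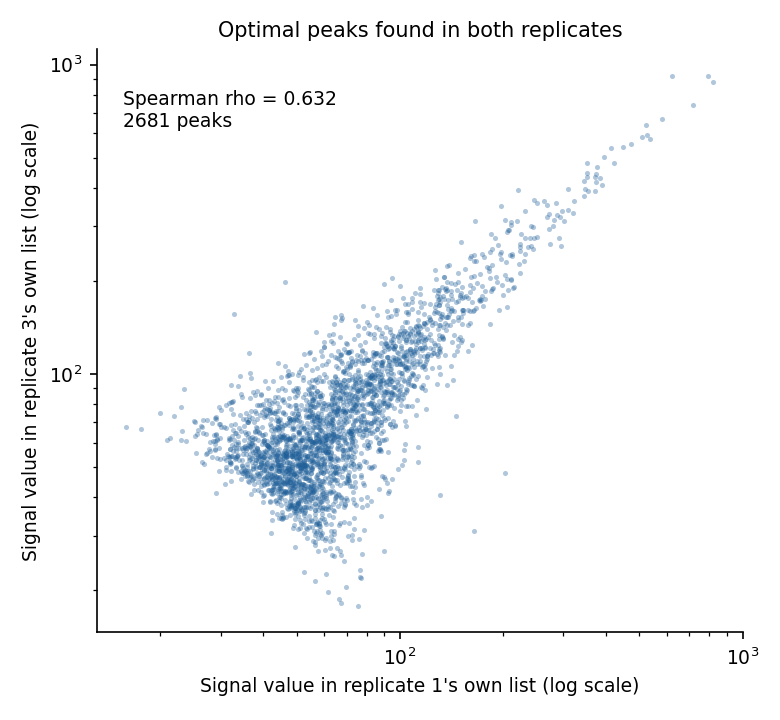
Signal value of each of the 2681 optimal peaks found in both replicates, in replicate 1's own list (x axis, log scale) and in replicate 3's (y axis, log scale). Each point is a peak; the strongest peaks lie close to a line and the weaker ones spread widely, with a Spearman's rho of 0.632.

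At repo itself, 4 optimal peaks lay within 20 kb of the gene (FBgn0011701, 3R 18236192 to 18239602, plus strand), each of them upstream. The promoter peak at 18235772 to 18236167 had its summit 222 bp from the TSS and a signal of 94.1, rank 2198 of the optimal list. This peak ranked 2149 in replicate 1 and 2667 in replicate 3. Its summit window held 0 of the 14 fixed motifs. The strongest of the 4, at 18228813 to 18229208 with a signal of 285 (rank 233), was intergenic, 7181 bp upstream of repo and 2615 bp from the TSS of Mdh2, a malate dehydrogenase gene. That peak held the reported Repo site CAATTA 5 bp from its summit, in the sequence GACGCAACCAATTAAGCTTCGT at 18229008 to 18229029. Replicate 1's own list had its summit at 18229008, but replicate 3's had summits at 18228943 and 18229154. Over all optimal peaks, CAATTA was in 17.4% of summit windows and 16.1% of flanks. The peak also held a match to the site of Gcm, the factor that starts glial development, 37 bp from the summit, as GCCCGCAT in TTAAACTTGCCCGCATGTCACGAC at 18229040 to 18229063. Over all optimal peaks the Gcm site was in 0.742% of summit windows and 1.19% of flanks. The other peaks lay in promoters, 119 bp from the TSS of CG7183 (signal 243) and 12 bp from that of mTerf5 (signal 93.6). The CG7183 window held the homeodomain sites TAATTA and TAATGA, and the mTerf5 window held CACGTG. The upper 1348 peaks by signal contained the intergenic peak and the CG7183 peak but not the promoter peak of repo. Whether extra copies of the locus in the transgenic line raised any of these peaks was not tested. In 1 of the 4 windows, that of mTerf5, the Dref site TATCGATA was present, at 18223685 to 18223692.

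**Figure D2:**
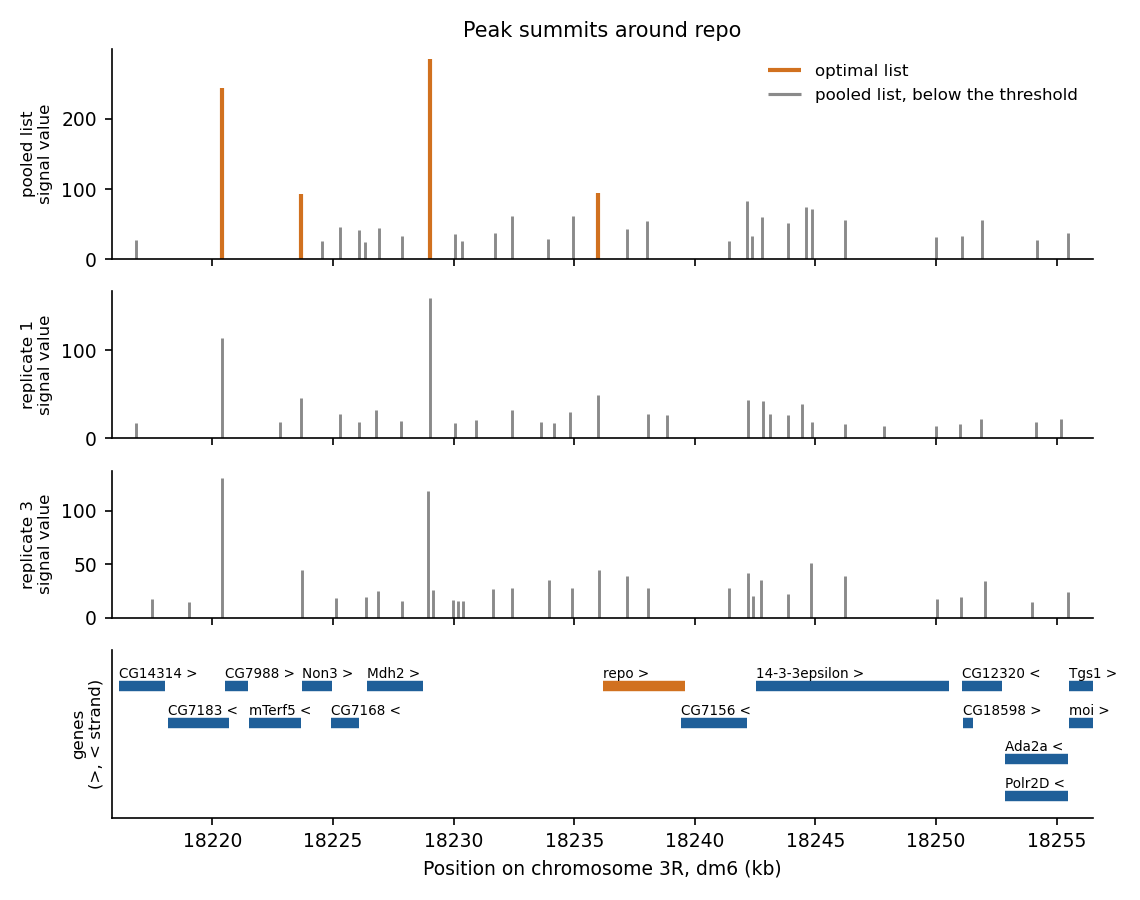
Peak summits around repo on chromosome 3R (x axis, kb, dm6) with their signal values (y axes) in the pooled list, with optimal peaks in orange, and in each replicate's own list; genes and strands are drawn at the bottom. The 4 optimal peaks lie upstream of repo, with signals of 285 and 243 at the stronger ones.

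Optimal peaks were concentrated at promoters and almost absent from coding exons. Promoters held 1487 summits (55.1%, 53.3 to 57.0%) against 26.4% of the weak peaks (odds ratio 3.42, exact adjusted p = 1.81e-194). Coding exons held 15 (0.556%, 0.337 to 0.916%) against 25.4% (odds ratio 0.0165, exact adjusted p = 1.73e-292). The 5' UTRs held 0.556% against 1.45% (exact adjusted p = 6.55e-05) and the 3' UTRs 0.519% against 1.78% (adjusted p = 8.45e-08). Introns held 29.6% against 30.4% (exact adjusted p = 0.357) and intergenic sequence 11.6% against 12.8% (adjusted p = 0.103), and neither passed the test. Intergenic sequence did pass as lower with either replicate left out (12.6% against 14.7% without replicate 1, exact adjusted p = 0.00365; 9.97% against 12.3% without replicate 3, 0.00064), and introns without replicate 3 (28.5% against 31.4%, 0.00256). Other exons held 2.11% against 1.75% (exact adjusted p = 0.227). The median distance from a summit to the nearest protein-coding TSS was 340 bp, and 1210 summits lay over 500 bp from any.

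**Figure D3:**
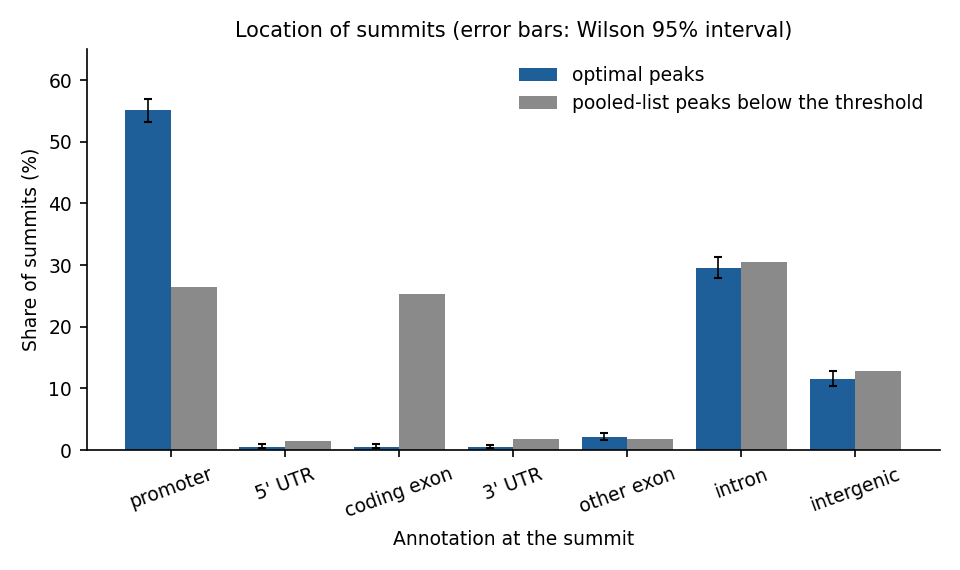
Share of summits (y axis, %) in each annotation class (x axis) for the 2697 optimal peaks (blue, with Wilson 95% intervals) and the 27302 weak pooled-list peaks (grey). Promoters hold 55.1% of optimal and 26.4% of weak peaks, and coding exons 0.556% and 25.4%.

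Of 13945 protein-coding genes, 2751 (19.7%) had an optimal summit between 2000 bp upstream and their end. Among the 15 gene lists, the cytoplasmic ribosomal protein genes passed the test for more bound genes than length-matched lists. Of these 93 genes, 57 (61.3%) were bound, against 12.6 expected, a ratio of 4.54 (permutation p = 0.0001, the smallest that 10000 lists can give, adjusted 0.0015). Matched on the number of pooled-list peaks in place of length the ratio was 2.57, and among genes with a pooled-list peak 3.27, both with the same p. The pooled list contains the optimal peaks, so both settings depend in part on the counted peaks themselves. In each of the 57 the strongest summit lay in the promoter class, with a median signal of 168. RpS27 (552, 1 bp upstream of the gene at 3R 25245955 to 25247514), RpL23A (420), RpL32 (397) and RpL41 (396) had the highest signals. With only summits over 500 bp from a TSS, 1 of the 93 was bound against 1.13 expected.

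Glial genes were bound in part. Of the glial regulators and pan-glial genes, 7 of 15 were bound against 4.92 expected (ratio 1.42, adjusted permutation p = 0.579), and of the surface glia and septate junction genes 9 of 20 against 5.23 (ratio 1.72, adjusted permutation p = 0.183). The astrocyte, cortex and wrapping glia genes had 2 bound of 18 against 5.11 expected (ratio 0.391, adjusted permutation p = 0.987 for more and 0.571 for fewer, unadjusted 0.0761), and without replicate 3 had 4 (ratio 0.762). None of these 3 lists passed the permutation test; the surface glia list had an unadjusted p of 0.0487. The ratio of that list turned to 0.636 (2 of 20 bound) in the upper 1348 peaks and to 0.484 at distal summits. Matched on pooled-list peaks it was 1.20, and that of the glial regulators turned to 0.926. That matching counts the optimal peaks as well, so these ratios cannot be read as an independent check. Other settings gave both lower and higher ratios, and neither list passed in any. Among genes with a pooled-list peak the surface glia list had 1.48 and the glial regulators 1.26. The surface glia list had 1.53 without replicate 1, and the glial regulators 1.34 in the upper 1348 peaks. The surface glia list had 2.01 with 1 kb either side of a TSS, 1.93 by nearest TSS and 2.23 at promoter summits (adjusted permutation p = 0.0705). The glial regulators had 1.98 by nearest TSS (adjusted permutation p = 0.0855) and 1.61 to 1.62 with either replicate left out.

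The bound glial genes of highest signal were moody and zfh1. moody (FBgn0025631, X 2044292 to 2050120), a receptor of the blood-brain barrier, had a promoter peak with a signal of 395 whose summit lay 170 bp upstream, at rank 108 in the optimal list and in replicate 1. zfh1, a zinc finger and homeodomain factor, had a signal of 309 in an intron at 3R 30781650 to 30781841, at rank 175 in replicate 1 and 1121 in replicate 3. Gs2, a glutamine synthetase, had 226, and apt, a transcription factor gene with 7 peaks, had 204. The Ets factor genes aop and pnt, which act in receptor tyrosine kinase signalling, had 4 peaks each, the highest at 177 and 168. ced-6, an adaptor for engulfment by glia, had 136, bou 120 and loco, a regulator of G-protein signalling, 119. The summit at bou lay 1073 bp from its own TSS and within 500 bp of another gene's TSS. The septate junction genes Lac and vari had 115.9 and 114.7, and Atpalpha, the sodium pump subunit, 112. The summit at vari lay 615 bp from its own TSS, also within 500 bp of another gene's TSS. wrapper, in the astrocyte, cortex and wrapping list, was the other bound member of that list at 94.4.

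Of the neuron genes, 3 of 18 (16.7%, 5.84 to 39.2%) were bound against 6.77 expected (ratio 0.443); the permutation test for more bound genes had an adjusted p of 0.987, and that for fewer a p of 0.0497 (adjusted 0.571). Across the 3 glial lists together 18 of 53 genes were bound (34.0%, 22.7 to 47.4%), against 15.3 expected from length-matched lists (one-sided permutation p = 0.240). The difference of 17.3 percentage points did not pass Fisher's exact test (p = 0.235, odds ratio 2.57). That test takes no account of interval length, and the glial share was above its length-matched expectation and the neuron share below. elav, an RNA-binding protein of neurons, had a promoter peak with a signal of 260. ChAT, which makes acetylcholine, had a peak of 155 inside the gene. nSyb, a synaptic vesicle protein, had one of 117 whose summit lay 1839 bp upstream, within 500 bp of another gene's TSS. With the 1348 upper peaks the difference was 2.10 points.

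Signalling and guidance genes missed the adjusted threshold. Of the Egfr, Fgf and Notch pathway genes 9 of 16 were bound against 4.64 expected (ratio 1.94, permutation p = 0.0175, adjusted 0.105); spi, an Egfr ligand, had a signal of 329 and aos, an Egfr inhibitor, 328. Of the axon guidance and adhesion genes 12 of 19 were bound against 7.24 (ratio 1.66, permutation p = 0.0211, adjusted 0.105), led by Wnt5 at 173 and unc-5 at 166. Matched on the number of pooled-list peaks in place of length, these ratios were 1.15 and 1.19. The pooled list contains the optimal peaks, so this matching uses part of the outcome and cannot decide whether the rise is real. Without replicate 1, 8 of the 19 axon guidance genes were bound (ratio 1.09, permutation p = 0.462), and with only the 1 kb either side of a TSS the Egfr, Fgf and Notch ratio was 1.23.

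Other tissues' lists held between 2 and 7 bound genes and none passed. Neuroblast genes had 2 of 18 bound against 4.54 expected (adjusted permutation p = 0.987), brat with a signal of 312 and insc with 106. Muscle genes had 5 of 23 against 6.81 (adjusted permutation p = 0.987). Mef2, a muscle transcription factor, had 5 peaks, the highest at 586, and kirre had 10, the highest at 328. The highest summit at Mef2 lay 1065 bp from its own TSS and within 500 bp of another gene's TSS. Hemocyte genes had 3 of 17 against 4.96 (adjusted permutation p = 0.987), with ush at 1698 and NimC4 at 138. Epidermis and trachea genes had 5 of 17 against 5.48 (adjusted permutation p = 0.987), with Fas3 at 147 and ovo at 123. Gut, fat body and Malpighian tubule genes had 6 of 16 against 4.76 (adjusted permutation p = 0.719), with LpR2 at 343 and fkh at 272.5. Germline genes had 3 of 14 against 3.36 (adjusted permutation p = 0.987), with bcd at 139 and swa at 136. Segmentation and homeotic genes had 7 of 28 against 7.78 (adjusted permutation p = 0.987), with dpp at 213 and sog at 175. Heat shock genes had 3 of 12 against 2.04 (adjusted permutation p = 0.719), with Hsp83 at 319 and Hsp27 at 251. Ratios of the neuroblast, muscle, epidermis and trachea, gut, germline and segmentation lists turned direction under at least 1 alternative, with the segmentation list at 1.93 by nearest TSS, and none passed. Lists of this size could miss a real rise: of simulated lists of 18 genes with a planted rise of 2 times, 56% passed before adjustment. Those genes were drawn from all protein-coding genes, without the interval lengths of the lists above. The share is therefore not the power of these tests after adjustment.

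**Figure D4:**
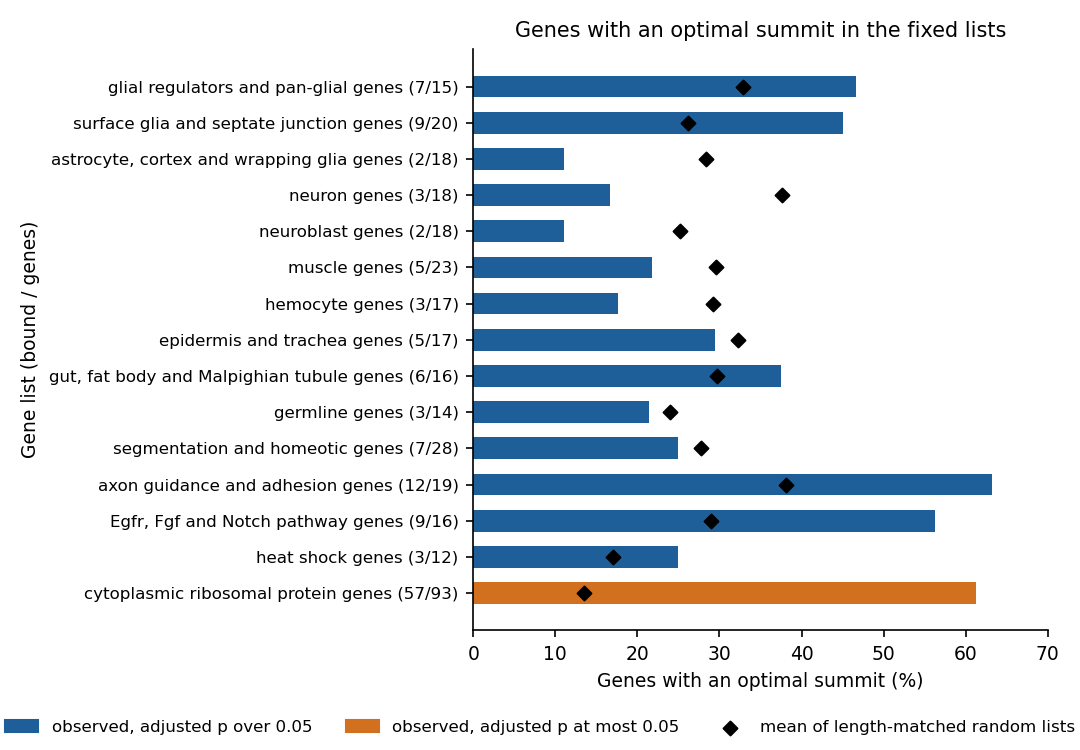
Percentage of genes with an optimal summit (x axis) in each of the 15 fixed lists (y axis, bound and total genes in brackets), with bars for the observed share and diamonds for the mean of 10000 length-matched random lists. The cytoplasmic ribosomal protein genes, at 61.3% against 13.5%, are in orange as past the adjusted threshold.

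The reported Repo site did not pass the test for a higher share at summits than beside them. CAATTA was present in 469 of 2697 summit windows (17.4%, 16.01 to 18.9%) and 16.1% of flanks (odds ratio 1.10, exact adjusted p = 0.223). Against the summits of weak peaks, whose GC content was higher (48.0% against 39.4%), it did pass, with an odds ratio of 1.42 (exact adjusted p = 7.79e-10). The homeodomain sites TAATTA (12.1% against 10.9%, exact adjusted p = 0.219) and TAATGA (11.5% against 11.03%, adjusted p = 0.699) did not pass against flanks either, and both passed against weak peaks (odds ratios 1.62 and 1.43, adjusted p = 1.27e-12 and 1.83e-07). Sites of promoter-binding factors passed against flanks: the Dref site TATCGATA was in 4.93% of summit windows against 0.667% of flanks (odds ratio 7.72, exact adjusted p = 3.77e-33), and the M1BP site GGTCACAC in 3.11% against 0.630% (odds ratio 5.07, adjusted p = 2.20e-16). Both passed with lower odds ratios against weak peaks (4.09 and 2.64, exact adjusted p = 2.12e-32 and 3.51e-12), and GGTCACAC had 2.67 in the upper 1348 peaks (adjusted p = 0.00559). The Snail E-box CACCTG was lower at summits, 6.04% against 8.79% (odds ratio 0.668, exact adjusted p = 5.39e-05), and did not pass in the upper 1348 peaks (odds ratio 0.731, adjusted p = 0.0761).

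The other 8 fixed motifs did not pass in the main test. They were the Gcm site ATRCGGGY (0.742% against 1.19%, exact adjusted p = 0.148), the Zelda site CAGGTA (4.12% against 4.58%, 0.503), the GAGA factor site GAGAGAG (5.30% against 4.32%, 0.140) and the Ets site CCGGAAG (0.853% against 1.13%, 0.459). The E-boxes CAGCTG (10.6% against 10.5%, 0.908) and CACGTG (3.04% against 2.89%, 0.795), the AP-1 site TGAGTCA (2.11% against 1.98%, 0.795) and the GATA site AGATAAG (2.08% against 2.91%, 0.0950) completed the set. GAGAGAG passed in other settings: with 200 bp either side (13.5% against 7.47%, odds ratio 1.94, exact adjusted p = 5.70e-17), without replicate 3 (odds ratio 1.59, 2.27e-05), at promoters (1.54, 0.00964) and against weak peaks (1.29, 0.00825). CAGCTG passed as higher with 200 bp either side (odds ratio 1.18, exact adjusted p = 0.0113) and as lower against weak peaks (0.800, 0.000953).

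The sites were also counted at promoter and distal summits apart. At the 1487 promoter summits, TATCGATA was in 8.47% of windows against 0.672% of flanks (exact adjusted p = 3.12e-40) and GGTCACAC in 5.38% against 0.672% (adjusted p = 2.85e-21). CAATTA was in 17.4% against 13.7% there (odds ratio 1.32, exact adjusted p = 0.00370); among the 192 six-base words with as many G and C bases, 103 had an odds ratio as high, as did 169 over all peaks and 190 at distal summits. TAATTA was in 12.8% against 9.41% (odds ratio 1.42, exact adjusted p = 0.00185), and 32 of 36 such words had an odds ratio as high; TAATGA was in 9.41% against 9.52% (adjusted p = 0.957). At the 1210 summits over 500 bp from a TSS none of the 14 motifs passed: CAATTA was in 17.4% against 19.0% of flanks (exact adjusted p = 0.906), TATCGATA in 0.579% against 0.661% and GGTCACAC in 0.331% against 0.579%. The difference between promoter and distal odds ratios was not itself tested. The flanks of promoter summits were centred 1000 bp away, and no other promoters served as background. The promoter shares therefore do not set these peaks apart from promoters in general.

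**Figure D5:**
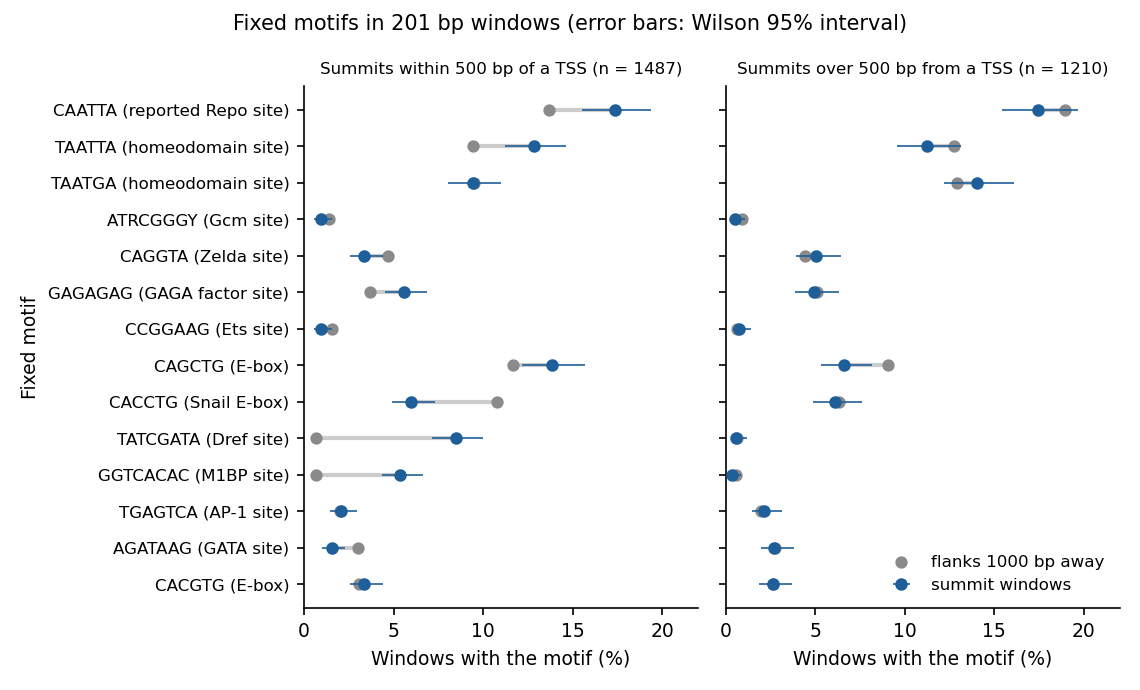
Percentage of windows (100 bp either side of the centre) that hold each of the 14 fixed motifs (x axis), for the 1487 summits within 500 bp of a TSS (left) and the 1210 others (right). Blue points are summit windows with Wilson 95% intervals and grey points are flanks 1000 bp away; TATCGATA and GGTCACAC stand apart from their flanks at promoters, at 8.47% and 5.38%.

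Among the 2080 six-base words, 444 were more frequent at summits than in flanks and 634 less frequent. The word of smallest p was ACACTG, in 609 windows (22.6% against 8.05% of flanks, odds ratio 3.33, exact adjusted p = 8.49e-68). ACAGTG followed, in 20.3% against 8.27% (odds ratio 2.82, exact adjusted p = 2.77e-48). Its reverse complement is CACTGT, so a single stretch ACACTGT holds both words. Their counts are therefore not independent, and windows with both were not counted apart. The AT-rich words AAAAAT (49.1% against 33.8%) and AAAATA (46.8% against 32.9%) were higher at summits, and CTCCTC was lower (3.93% against 11.7%); GC content was 39.4% at summits and 43.1% in flanks. At distal summits ACAGTG and ACACTG ranked first and second, in 22.1% against 8.39% and 20.4% against 7.48% of windows. At promoter summits CGATAG, which lies within an extended Dref site, ranked first (19.1% against 4.88%) and ACACTG second (24.3% against 8.51%).

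Peaks per Mb were similar on the large chromosome arms and lower on chromosome 4; evenness over the arms was not tested. There were 21.9 optimal peaks per Mb on 2L, 20.4 on 2R, 19.5 on 3L, 20.1 on 3R and 19.7 on X. Chromosome 4 held 9 peaks, 6.68 per Mb. The X held 17.2% of optimal peaks (15.8 to 18.6%) against 16.4% of weak peaks (Fisher's exact test, p = 0.276). Without replicate 1 it held 18.5%, which passed as higher (exact p = 0.000311), and without replicate 3 the direction turned, at 16.2% (exact p = 0.956). Chromosome 4 held 0.334% against 0.429% (Fisher's exact test, p = 0.638); weak peaks there were at 86.8 per Mb against 206 on 3R.

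The authors' dm3 lists gave nearly the same picture in number and signal. The optimal list held 2682 peaks on dm3, and signal values at equal rank differed by a median of 0.423% and at most 1.30% between builds. The replicates' own highest peaks shared 69.9% on dm3 against 69.7% on dm6.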

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

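For 60 results, 361 values were computed under alternatives, and 287 of them stayed the same. That means the same direction and side of the threshold or, for counts and rho, a change within a set tolerance. Of the others, 39 turned direction, 19 passed the threshold only under the alternative, 2 lost it and 14 moved. Values that turned were counted only as turned. Among these, TATCGATA, GGTCACAC and the ribosomal protein list also lost their calls at distal summits, and CAGCTG also passed against weak peaks. Most of those that turned had not passed the threshold in the first place. The cause was not tested for any change below except where the alternative itself uses fewer peaks. The upper part of the list by signal holds 1348 peaks by construction. The ratio of bound to expected ribosomal protein genes stayed between 2.57 and 6.29 under every setting but distal summits, where it was 0.886 and 0 lists passed. Alternatives that split summits by distance to a TSS for lists and words, that used promoter summits for motifs, or that varied location classes and named genes were chosen after seeing the data.

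Gene list ratios turned as follows. With 1 kb either side of a TSS, gut genes had 0.580 and germline genes 1.10; with the nearest TSS, muscle genes had 1.09, epidermis and trachea genes 1.34 and segmentation genes 1.93. With the upper 1348 peaks, surface glia genes had 0.636 and germline genes 1.05. Among genes with a pooled-list peak, epidermis and trachea genes had 1.01, and matched on pooled-list peaks, glial regulators had 0.926. Both settings count the optimal peaks among the pooled-list peaks. With distal summits, surface glia genes had 0.484, neuroblast 1.04, muscle 1.27, epidermis and trachea 1.87, germline 1.11 and segmentation genes 1.49. With promoter summits gut genes had 0.576, and with either replicate left out 0.834 to 1.26. With either replicate left out, axon guidance genes had 1.09 to 1.65 and astrocyte, cortex and wrapping glia genes 0.388 to 0.762. The glial minus neuron difference ran from 0.210 to 24.8 points and never passed (p from 0.0525 to 1).

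The number of motifs higher at summits, 2 in the main test, was 5 with 200 bp either side, 6 against weak peaks, 0 at distal and 5 at promoter summits. The number lower, 1 in the main test, was 4 against weak peaks, 0 with the upper 1348 peaks, 0 at distal and 2 at promoter summits, and 1 to 2 with either replicate left out. Against weak peaks, whose GC content was higher, CAATTA (1.42), TAATTA (1.62), TAATGA (1.43) and GAGAGAG (1.29) passed as higher, and ATRCGGGY (0.532), CCGGAAG (0.4997) and CAGCTG (0.800) as lower; TATCGATA (4.09) and GGTCACAC (2.64) still passed. With 200 bp either side TAATTA (1.15), GAGAGAG (1.94) and CAGCTG (1.18) passed; at promoters CAATTA (1.32), TAATTA (1.42), GAGAGAG (1.54) and, as lower, AGATAAG (0.503) passed. GAGAGAG passed without replicate 3 (1.59) and ATRCGGGY, as lower, without replicate 1 (0.454), while CACCTG lost its call in the upper peaks (0.731) and at distal summits (0.965). Odds ratios turned for TAATTA (0.932 with 50 bp, 0.865 distal), CAGCTG (0.964 with 50 bp, 0.800 against weak peaks, 0.708 distal) and TAATGA (0.967 with 200 bp, 0.988 at promoters). They also turned for TGAGTCA (0.995 with 200 bp, 0.966 in the upper peaks, 0.877 to 1.05 with either replicate left out), AGATAAG (1.00 against weak peaks) and GAGAGAG (0.992 in the upper peaks, 0.974 distal). At distal summits they turned for CAATTA (0.902), CAGGTA (1.15), CCGGAAG (1.20), TATCGATA (0.874) and GGTCACAC (0.570), and with either replicate left out CACGTG had 0.962 to 1.20. Distal summits gave 233 words higher and 253 lower.

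Spearman's rho over all matched peaks was 0.642 with summits within 100 bp. The X held 16.2 to 18.5% of peaks with either replicate left out, passed as higher without replicate 1 (Fisher's exact test, two-sided, p = 0.000311) and turned direction without replicate 3. Chromosome 4 held 0.445% of the upper peaks. No paired analysis was possible because the series holds 1 group. Read depth is unknown here, so it could not be compared between replicates.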

Other observations

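The families, genes and patterns below were picked, and every one of their tests chosen, only after the result was seen; 1 criterion, for extra copies of the repo locus, was made stricter after its result was known, which moved its verdict from fitting to undecided. Among 22 gene families set by symbol, 2 had more bound genes than length-matched lists: the mitochondrial ribosomal protein genes, 21 of 73 against 7.94 expected (ratio 2.64, adjusted permutation p = 0.00147), and the nucleoporin genes, 11 of 21 against 4.62 (ratio 2.38, adjusted permutation p = 0.0125). Translation factor genes had 17 of 52 (ratio 1.64, adjusted permutation p = 0.0934), vacuolar ATPase genes 10 of 33 and Rab genes, of vesicle traffic, 10 of 31. Proteasome, respiratory chain, tRNA synthetase, Sm and snRNP, RNA polymerase, chaperonin, tubulin, actin, Hsp, odorant-binding protein and Tweedle genes did not pass. Fewer bound genes were found in 6 families. Gustatory receptors had 0 of 60 (a count of 0 allows up to 5%), ionotropic receptors 1 of 60 and odorant receptors 2 of 59. Cuticle proteins of the Cpr group had 1 of 70, cytochrome P450 genes 4 of 85 and histones 2 of 118. Whether reads could be placed uniquely in gene copies of similar sequence, such as histone genes, was not tested. The histone count is therefore not read as absence of binding.

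Genes with many peaks away from a TSS included Raf, a kinase of receptor tyrosine kinase signalling, with 11 peaks, 10 of them over 500 bp from a TSS (X 2295466 to 2343870). CG1677 had 10 peaks, 9 of them distal, and the transcription regulator genes sbb and ush had 8 each, 7 of them distal. Hr4, a nuclear receptor, and apt had 7 each, 6 of them distal. These counts were not tested against gene length.

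Peaks at ribosomal protein promoters may be background at promoters active in every cell. The other 10 constitutive families together held 103 bound genes of 381 against 58.0 expected (ratio 1.78, one-sided permutation p = 0.0001, the smallest possible). Of these families, only the mitochondrial ribosomal protein and nucleoporin genes passed alone. The ratio of 4.54 for the ribosomal genes was higher. Binding of tagged Repo at such promoters would give the same excess, and no control track was used here. The value therefore cannot tell background from binding. CAATTA was in 17.5% of the 57 summit windows and 16.7% of their flanks, so a role of that site cannot be told apart from none. The 57 genes had 57 distinct summits, so the count does not come from a few peaks shared among these genes. Peaks shared with other neighbouring genes were not counted apart, and by nearest TSS 51 of the 93 genes were bound. TATCGATA was in 26.3% of these windows and 1.75% of their flanks, and other promoters were not compared.

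The words ACAGTG and ACACTG at distal summits could come from base composition, repeats or the exact M1BP site. Shuffled windows argued against composition as the whole cause. Repeats could be judged only in windows without soft-masked bases, where both words still passed. The exact site was too rare at distal summits to account for the words. The 2 words overlap in sequence, so their results are not independent of each other. In windows shuffled with their dinucleotide counts kept, the highest odds ratio of 20 shuffles was 1.56, against lower 95% bounds of 2.54 and 2.58 for the measured ones. In windows without soft-masked bases, 214 of the 1210 at summits, the lower of the odds ratios was 2.64 (Fisher's exact test, two-sided, p = 0.000168). The other windows were left out of that test. Of the 247 distal windows with ACACTG, 0.81% held GGTCACAC, against the 63.4% of them that lay over the flank level; variants of that site were not tested. The tests of composition and of this site replaced earlier ones that could hardly have come out otherwise. In those, no other of 632 words with as many G and C bases was as high, without the 2 words and their shifted neighbours. Leaving out windows with GGTCACAC, 4 at summits and 14 in flanks, gave 3.31 for ACACTG. The later test of this site was settled beforehand too, since GGTCACAC was in only 4 of the 1210 distal summit windows.

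Weak peaks were dense around repo, with 27 within 20 kb against a mean of 11.8 per gene, which extra copies of the locus in the transgenic line could give. As many weak peaks were found around 0.904% of genes; the share was 0.516% for the whole pooled list, 0.172% in replicate 3, 1.34% in replicate 1 and 7.65% for optimal peaks. The first criterion, at most 1% for weak peaks alone, was met, and the stricter one, at most 1% in both replicates as well, was not, so the explanation stays open. CAATTA was in 14.8% of the weak summit windows against 12.9% elsewhere, and 2.499% of regions with as many transcription starts had as many weak peaks; neither decided. Beyond the sequence sites above, no biological explanation was tested, since the series holds 1 group.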
